A study of Capra hircus with 12 samples.

How the data were processed

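Total RNA from black goat (Capra hircus) testis was sequenced at 4 ages, named neonatal, prepuberty, puberty and postpuberty in the labels, with titles that carry D3, D30, D90 and D180. RNA was extracted with TRIzol and made into libraries with a kit for long non-coding RNA, per the labels' protocols. Of the 12 samples in the labels, 11 had a table that was used here. Puberty replicate 1 was not analysed here, so puberty had 2 libraries and each of the other ages had 3.

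Each table held 1 FPKM value (fragments per kilobase of locus, scaled to the size of the library) per locus, as deposited by the authors, with no header. HISAT2 2.1.0 (a spliced read aligner) and StringTie 2.1.1 (a transcript assembler) are named in the submitters' processing notes. The genome build, the annotation, the read counter and any filter on loci are not given in the sources used here. All 11 tables listed the same 24116 loci in the same order. Of these, 22286 had identifiers of the MSTRG form that StringTie gives to assembled loci, and 1830 had identifiers made of the word gene and a number. None of the identifiers matched the gene table of assembly ARS1.2 (28911 genes), so 0 loci have a symbol, a biotype or a position here. Whether a locus is coding, long non-coding or another kind is not stated in the tables. The tests planned for 27 fixed lists of testis genes, for biotypes and for the X chromosome were therefore not run, and 0 members of those lists could be matched.

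The depth was read from the values themselves. In low values, the ratio between libraries takes steps that correspond to whole reads, and the most frequent ratio gives the relative worth of 1 read. With these steps, the values of 24114 loci (100.0%) were whole multiples of 1 read in all 11 libraries. The distance from a whole number was under 0.002 reads in every library for 24111 of them and at most 0.00793 reads for the rest. For 4 loci the length was searched directly, with a tolerance of 0.02 reads. A single set of library totals then also made the locus lengths whole, within 0.01 bases, for 24110 loci. The totals so obtained lay within 0.00247 of whole numbers in every library, although nothing in the procedure forced them to be whole. They are called scaling totals below, and the reads and lengths obtained are called recovered reads and implied lengths. A recovered length can be a fraction of the true one where all counts of a locus share a factor, and 283 loci had an implied length under 200 bases. Scaling totals ran from 19128357 reads in neonatal replicate 3 to 35614224 in puberty replicate 2. At the median implied length of 1346 bases, an FPKM of 1 stood for 25.7 to 47.9 reads. The reads on the listed loci made up 13.5% to 25.6% of the scaling totals, so the tables hold part of each library.

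Loci with an FPKM of at least 1 in at least 2 libraries were tested, which kept 12954 loci and left out 11162. Values were analysed as log2(FPKM + 1), and all fold changes on the log2 scale refer to that scale, which understates the change of low loci. limma 3.58.1 in R 4.3.3 was fitted to all 11 libraries with 1 mean per age (7 residual degrees of freedom) and a variance trend. A locus was called at a Benjamini-Hochberg adjusted p under 0.05 (adjusted over the 12954 loci of each comparison) and a change of at least 1 on the log2 scale. All tests were two-sided. The comparisons were the 3 consecutive steps and postpuberty against neonatal, plus an F test over the 4 ages, in which a called locus also needed a range of group means of at least 1. The design, the thresholds and most alternatives were set before the data were examined. Nothing in the labels says whether the replicates of an age came from separate animals, so p-values measure only the spread between these samples. No pair of libraries agreed within sampling noise: chi-square per locus was at least 15.2 for every pair within a group.

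The rule for the loci named in the text, set before the data were examined, takes genes with symbols and, in each comparison, the 5 called loci with the highest mean FPKM. With no symbols, only the latter part applied. Of these 5, the text names the first 2 that rose and the first 2 that fell, in order of mean FPKM. Where fewer than 2 did, the place was filled, in order of size, by the largest rise or fall on the log2 scale among called loci whose libraries did not overlap. That filling was decided after the values were seen, and it covers gene7384, gene13049, MSTRG.68458 and MSTRG.198760.

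The limma procedure was tested on simulated data with 200 changed loci. Each simulation took the real mean of the younger age compared as the level of every library, before the changes. The real scaling totals and 1 dispersion for all loci (0.0329) were used. Unchanged loci thus had no difference between ages, and fewer loci passed the filter than in the real data. The counts below hold for that simpler setting. In the simulation of puberty against prepuberty (5914 loci), 34 of 34 loci raised 4-fold and 33 of 33 raised 8-fold were called, against 18 of 33 lowered 4-fold, 27 of 33 lowered 8-fold and 6 of 34 raised 2-fold, with 0 false calls among 121. In that of postpuberty against puberty (7470 loci), 33 of 34 loci raised 4-fold and 16 of 33 lowered 4-fold were called, with 1 false call among 113. In that of prepuberty against neonatal (7071 loci), 34 of 34 raised 4-fold and 22 of 33 lowered 4-fold were called, and in that of postpuberty against neonatal (7054 loci), 33 of 34 and 22 of 33.

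Alternatives covered the pseudocount, the filter, 3 scalings between libraries, the variance trend, a fit of only the groups compared, a block for the replicate number, the omission of each library and the fold threshold. Of the scalings, TPM gave every library the same FPKM sum, larger than any deposited one. The pseudocount stayed at 1, so TPM also lowered the weight of the pseudocount. After the data were seen, 4 more were added: recovered reads thinned to the smallest scaling total, limma's voom on the recovered reads, a total without the 4 loci of highest FPKM, and the omission of prepuberty replicate 1 together with neonatal replicate 1. Intervals and limits from reads cover counting error only. A locus with no read is given against a floor of 3 reads summed over the libraries of its group. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.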

Results

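RNA was measured in testes of black goats at 4 ages to ask which loci change as the testis develops from birth through puberty. There were 3 neonatal libraries (titles D3), 3 prepuberty libraries (D30), 2 puberty libraries (D90) and 3 postpuberty libraries (D180). Scaling totals averaged 19765324 ± 712853 reads (SD, n = 3) in neonatal, 26346398 ± 723101 (n = 3) in prepuberty, 35070316 ± 769201 (n = 2) in puberty and 31039224 ± 3363510 (n = 3) in postpuberty libraries. The loci carry assembly identifiers without gene names, genome positions or annotation, so they are described as groups by their behaviour and by identifier type.

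The 11 libraries fell into a younger pair of ages and an older pair. Across the 12954 tested loci, Pearson correlations of log2(FPKM + 1) between libraries of the same age were 0.92 to 0.94 in neonatal, 0.95 to 0.96 in prepuberty, 0.89 for the puberty pair and 0.92 to 0.93 in postpuberty testes. Neonatal and prepuberty libraries correlated with each other at 0.86 to 0.92, and puberty and postpuberty libraries at 0.87 to 0.91. Between prepuberty and puberty libraries the correlation was only 0.09 to 0.16, and Spearman correlations of the same pairs were -0.15 to -0.09. The filter drops loci that are low at all ages and keeps loci that are high at some, which can lower correlations between ages. Correlations without the filter were not computed. These are correlations across loci, which are not independent replicates. The first principal component held 85.6% of the variance and separated the younger from the older ages. On the axis from the prepuberty mean to the postpuberty mean, the puberty libraries lay at 84.6% and 84.4% of the way, and the postpuberty libraries, each placed against the mean of the other 2, at 95.2% to 103.5%.

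More of the listed loci had a value above 0 in the older testes. A value above 0 was found for 65.4% ± 1.43 (SD, n = 3) of the 24116 loci in neonatal and 65.6% ± 1.95 (n = 3) in prepuberty libraries, against 88.0% ± 2.30 (n = 2) in puberty and 89.8% ± 0.850 (n = 3) in postpuberty libraries. The highest library of the younger ages detected 16331 loci and the lowest of the older ages 20830. With recovered reads thinned to the same total of 19128357, the means were 15710 ± 401 loci in neonatal, 15262 ± 441 in prepuberty, 20358 ± 646 in puberty and 21065 ± 152 in postpuberty libraries. Loci with at least 5 reads after thinning numbered 11721 ± 391, 10948 ± 331, 15812 ± 767 and 17174 ± 274 in that order. Loci with a deposited FPKM of at least 1 numbered 5961 ± 406, 4877 ± 295, 5835 ± 474 and 8402 ± 714. By that last count, puberty libraries did not exceed neonatal ones. For neonatal against postpuberty, 3 libraries against 3, an exact permutation test cannot give a two-sided p under 0.1.

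**Figure D1:**
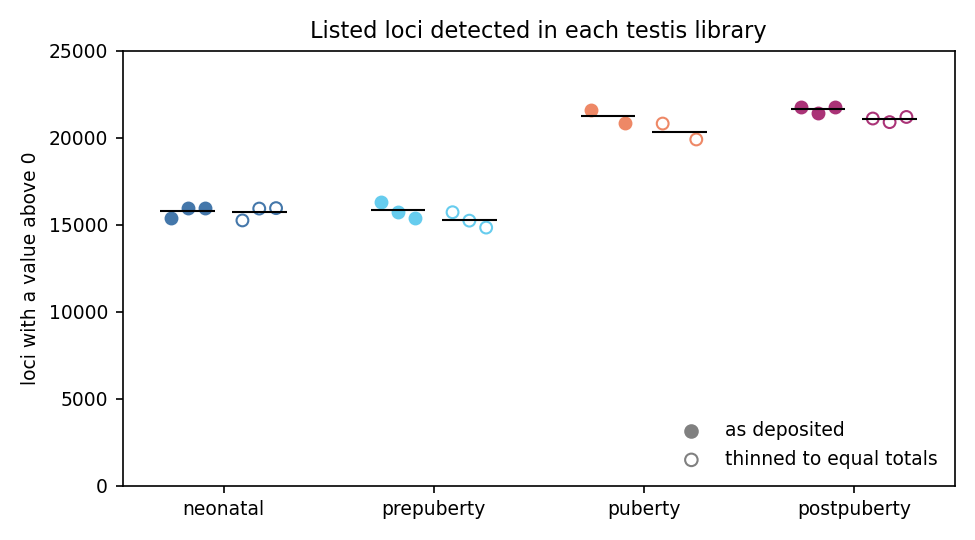
Number of the 24116 listed loci with a value above 0 (y axis) in each testis library, by age (x axis), as deposited (filled points) and after thinning the recovered reads to the same total (open points), with lines at the group means. The neonatal and prepuberty libraries lie at or below 16331 loci and the puberty and postpuberty libraries as deposited at or above 20830.

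A few very abundant loci declined with age. The 4 loci with the highest FPKM took 10.004% ± 0.931 (SD, n = 3) of the scaling total in neonatal, 7.45% ± 0.807 (n = 3) in prepuberty, 3.71% ± 0.969 (n = 2) in puberty and 2.66% ± 0.472 (n = 3) in postpuberty libraries. The most abundant of them in neonatal testes, MSTRG.335283 (implied length 355 bases), went from 69775 ± 1826 FPKM in neonatal through 29924 ± 3938 in prepuberty and 13156 ± 1872 in puberty to 9708 ± 1520 in postpuberty testes. All fold changes below rest on the authors' scaling. The median log2 change of the tested loci was -0.03 for prepuberty against neonatal, 0.26 for puberty against prepuberty, 0.18 for postpuberty against puberty and 0.50 for postpuberty against neonatal. In the same order, these medians were -0.02, 0.54, 0.08 and 0.75 after median of ratios scaling and 0.19, 0.91, 0.37 and 1.92 after rescaling to TPM. A pseudocount of 0.1 with the authors' scaling gave -0.11, 0.60, 0.36 and 0.97. The TPM medians thus reflect in part a lower weight of the pseudocount. Quantile normalization, which gives all libraries the same distribution, brought them to -0.01, -0.01, -0.02 and 0.07.

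Prepuberty against neonatal asks what changes before puberty. Of the 12954 loci, 107 rose, 161 fell and 12686 did not pass the test. MSTRG.407276 rose from 17.9 ± 3.18 FPKM (SD, n = 3) to 115 ± 69.4 (n = 3), a log2 change of 2.41 ± 0.48 (SE, limma adjusted p = 0.0113). MSTRG.414056 rose 2.15-fold, from 24.8 ± 5.66 to 53.3 ± 7.18 FPKM (limma adjusted p = 0.0268), and stood at 8.05 ± 4.51 (n = 2) in puberty. Among loci that fell, MSTRG.335283 was 2.33-fold lower in prepuberty (limma adjusted p = 0.00451). gene7384 (implied length 125 bases) fell from 6.97 ± 6.34 FPKM, 51 reads in all, to 0.0998 ± 0.173, a single read (limma adjusted p = 0.0299). With 1 library omitted, MSTRG.407276 lost its call without prepuberty replicate 3, with a log2 change of 2.28 (limma adjusted p = 0.0523). MSTRG.414056 lost its call without neonatal replicate 1 (log2 change 0.92), neonatal replicate 2 (1.10), or prepuberty replicate 1 (1.14), 2 (0.98) or 3 (1.14), against 1.09 with all libraries, at limma adjusted p of up to 0.0731. It also lost it with a pseudocount of 0.1 (limma adjusted p = 0.0505) and under quantile normalization (0.0517). gene7384 lost its call without neonatal replicate 2 (log2 change -1.76) or 3 (-2.22) or prepuberty replicate 1 (-2.35), 2 (-2.35) or 3 (-2.54), against -2.42 with all libraries, at limma adjusted p of up to 0.0906. Its adjusted p also rose slightly above 0.05 when a puberty library, or postpuberty replicate 2 or 3, left the fit, and in the test without a filter (0.0524), with the same fold. The call of MSTRG.335283 ended under quantile normalization (log2 change 0.00, since this method sets values by rank and the locus ranked highest in all 6 libraries), under TPM (-0.48) and in the test without a filter (limma adjusted p = 0.0604). Loci with a gene number rose more often than loci with an MSTRG identifier, at 2.102% of 999 against 0.719% of 11955, and fell at shares of 1.30% and 1.24% (Fisher's exact test over the 3 outcomes by resampling, p = 1e-04, the smallest the resamples can give, with loci taken as independent). Of the calls, 39.9% were higher in prepuberty. That share was 52.0% under median of ratios scaling, 66.7% under quantile normalization and 91.0% after rescaling to TPM. TPM divides by the FPKM sum, whose mean fell from 127680 in neonatal to 75861 in prepuberty libraries. Without the top 2 loci of each library, the fall was only from 32295 to 28308. The share under TPM thus rests largely on the fall of the most abundant loci. With only the 6 libraries of these ages in the fit, limma called 11 rises and 8 falls, with none of the 4 named loci among them. Without neonatal replicate 1 the falls numbered 246, and without prepuberty replicate 3 they numbered 101.

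Puberty against prepuberty asks what changes as the testis enters puberty, and it held the most calls of the 3 steps. Of the 12954 loci, 3067 (23.7%) rose, 1681 (13.0%) fell and 8206 did not pass the test. The median log2 change was 1.47 among loci that rose and -1.31 among those that fell. Changes of at least 8-fold on the log2(FPKM + 1) scale were reached by 301 loci that rose and 19 that fell. gene13049 (implied length 313 bases) rose from 0.682 ± 0.763 FPKM (SD, n = 3; 17 reads in all) to 440.3 ± 0.650 (n = 2), a log2 change of 8.13 ± 0.29 (SE, limma adjusted p = 4.49e-09). gene21247 was already abundant and rose 2.84-fold, from 152 ± 11.8 to 430.4 ± 8.99 FPKM (limma adjusted p = 5.73e-06). MSTRG.385323 (implied length 7781 bases) fell 4.84-fold, from 3875 ± 308 to 801 ± 107 FPKM (limma adjusted p = 6.52e-06), after 3688 ± 892 in neonatal testes; its call ended by fold under quantile normalization (log2 change -0.65). MSTRG.335283 fell 2.27-fold (limma adjusted p = 0.000612), a call that median of ratios scaling (log2 change -0.46), quantile normalization (-0.38) and TPM (-0.87) each ended.

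Loci with a gene number were split evenly at this step, with 20.1% of 999 higher and 21.02% lower, whereas MSTRG loci rose more often than they fell, at 23.97% and 12.3% of 11955 (Fisher's exact test by resampling, p = 1e-04, the smallest the resamples can give). The share of calls that were higher was 64.6%; it was 85.2% under median of ratios scaling and 45.7% under quantile normalization. In prepuberty replicate 1, 97 loci that were near absent from the other younger libraries and abundant in the older ones stood at 0.382% of their mean older level. With loci chosen in the same way without the library in question, prepuberty replicates 2 and 3 stood at 0.0407% and 0.0350% and the neonatal libraries at 0.0282% to 0.0592%, prepuberty replicate 1 taking no part in that choice. Without that library, 3082 loci rose and 1689 fell, and 4597 of the 4748 calls remained with the same sign.

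**Figure D2:**
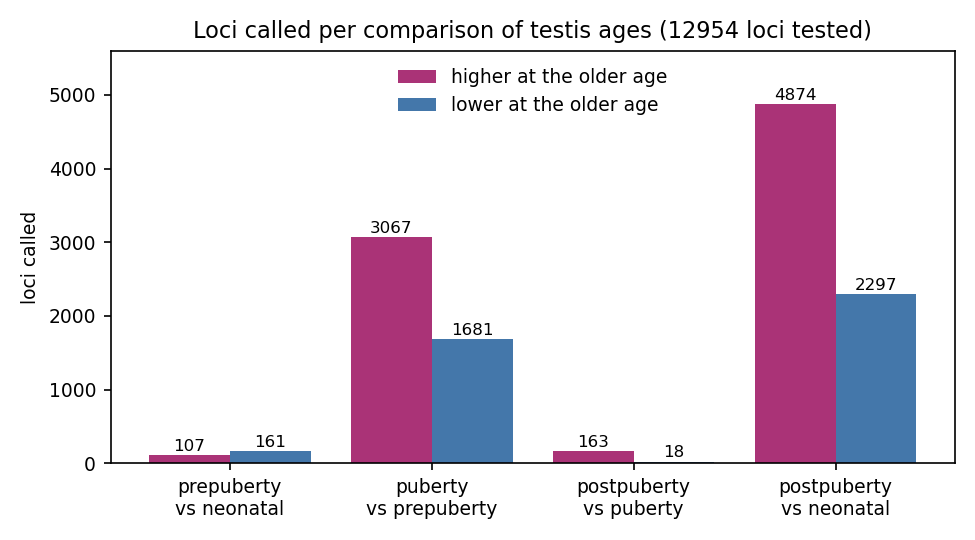
Number of loci called by limma (y axis) as higher or lower at the older age in each comparison (x axis), out of 12954 tested. The step from prepuberty to puberty holds 3067 rises and 1681 falls, against 107 and 161 at the step before and 163 and 18 at the step after.

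Postpuberty against puberty asks what changes once puberty has been reached. Of the 12954 loci, 163 rose, 18 fell and 12773 did not pass the test. MSTRG.98741 rose 2.91-fold, from 8.93 ± 3.78 FPKM (SD, n = 2) to 26.001 ± 8.45 (n = 3; limma adjusted p = 0.0395). MSTRG.8146, which had no read in the 6 younger libraries, rose 2.02-fold, from 11.6 ± 7.10 to 23.5 ± 4.95 FPKM (limma adjusted p = 0.0344). gene27 fell 2.36-fold, from 38.6 ± 12.8 to 16.4 ± 6.05 FPKM (limma adjusted p = 0.0208). MSTRG.68458 was highest in puberty, with 27.2 ± 0.673 FPKM (n = 2) there, 1.5004 ± 1.56 (n = 3) in postpuberty and 0.0931 ± 0.0962 (n = 3) in prepuberty testes, and fell with a log2 change of -3.69 ± 0.38 (SE, limma adjusted p = 0.00159). Without puberty replicate 3, MSTRG.98741 had a log2 change of 1.05 (limma adjusted p = 0.266), against 1.45 with all libraries, and MSTRG.8146 had 0.46 (limma adjusted p = 0.205), against 1.06, so both lost their calls. Both also lost them without postpuberty replicate 2 (log2 changes 1.22 and 1.09) or 3 (1.44 and 0.91). Omitting neonatal replicate 2 or a prepuberty replicate, or for MSTRG.8146 neonatal replicate 3, left the fold as it was but raised the adjusted p slightly above 0.05 (up to 0.0612). gene27 lost its call without puberty replicate 3 (log2 change -0.89, limma adjusted p = 0.157) and, by fold, without postpuberty replicate 3. Under median of ratios scaling, quantile normalization and TPM, MSTRG.98741 (log2 changes 1.25, 0.94 and 1.54) and MSTRG.8146 (0.86, 0.64 and 1.13) were not called, nor was gene27 under TPM (-1.28). Under TPM the folds of MSTRG.98741, MSTRG.8146 and gene27 were no smaller than with the authors' scaling, and only the adjusted p passed 0.05. These 3 loci also lost their calls with a pseudocount of 0.1 (limma adjusted p = 0.378, 0.0929 and 0.0639) and with voom on recovered reads (0.158, 0.0707 and 0.0556). The replicate block ended the calls of MSTRG.98741 and MSTRG.8146, and the test without a filter and the total without the 4 highest loci that of MSTRG.98741. Identifier types did not differ by the test at this step, where 0.701% of loci with a gene number and 1.305% of MSTRG loci rose (Fisher's exact test by resampling, p = 0.1679). Of the calls, 90.1% were higher, and 55.4% under quantile normalization, which brings the median change near 0 by construction. This step rests on 2 puberty libraries: without puberty replicate 2, 448 loci rose and 34 fell. With only these 5 libraries in the fit, limma called 0 loci (2514 at an unadjusted p under 0.05), while voom on recovered reads of all libraries called 244 rises and 15 falls.

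Postpuberty against neonatal spans the whole series. Of the 12954 loci, 4874 (37.6%) rose, 2297 (17.7%) fell and 5783 did not pass the test. gene13049 rose from 0.871 ± 0.363 FPKM (SD, n = 3) to 509.1 ± 7.62 (n = 3; log2 change 8.11 ± 0.26 SE, limma adjusted p = 1.13e-09). MSTRG.198760 had no read in the neonatal libraries and 204 ± 29.1 FPKM in postpuberty testes, at least 3382-fold higher against a floor of 3 reads over the neonatal libraries (limma adjusted p = 3.44e-10). MSTRG.335283 fell 7.19-fold (limma adjusted p = 2.44e-07), a call that ended by fold under quantile normalization (log2 change -0.50). MSTRG.178147 fell 2.57-fold, from 25610 ± 1599 to 9956 ± 2795 FPKM (limma adjusted p = 0.00056), and its call ended under median of ratios scaling (log2 change -0.86) and TPM (-0.34). Its direction reversed under quantile normalization (0.50), where it exchanged ranks with MSTRG.335283 in some older libraries. Of loci with a gene number, 26.1% rose and 23.0% fell, against 38.6% and 17.3% of MSTRG loci (Fisher's exact test by resampling, p = 1e-04, the smallest the resamples can give). Of the calls, 68.0% were higher; that share was 80.6% under median of ratios scaling and 44.7% under quantile normalization.

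**Figure D3:**
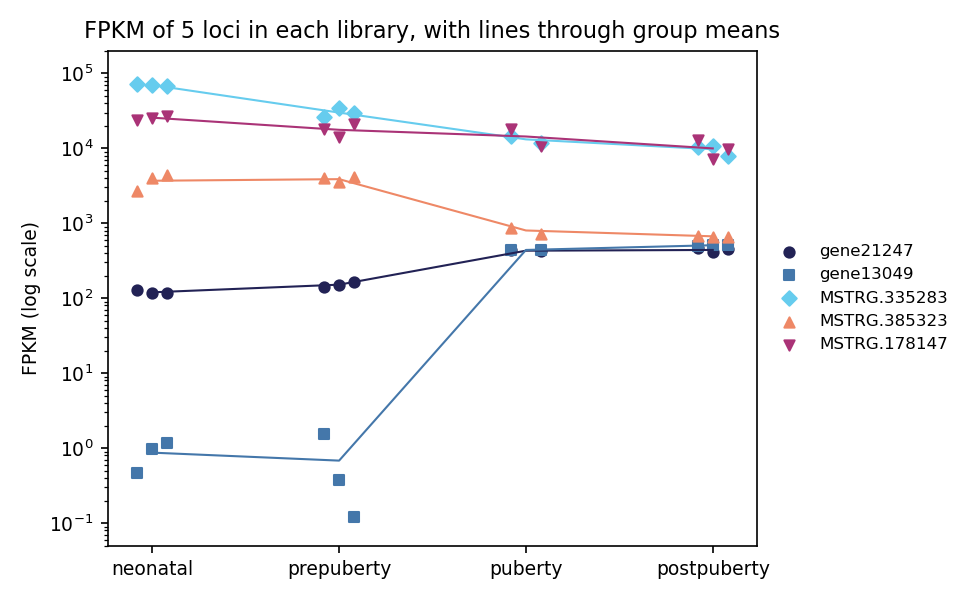
FPKM on a log scale (y axis) of 5 loci in each library, by age (x axis), with points for libraries and lines through the group means. gene13049 lies below 1.6 FPKM in every neonatal and prepuberty library and above 439 in every older library, while MSTRG.335283 falls from a mean of 69775 to 9708 FPKM.

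The rise and fall at puberty can be compared with the whole span on separate libraries, since the puberty and prepuberty libraries enter no part of the postpuberty and neonatal means, although the fit shares 1 estimate of the spread. Of the 3067 loci that rose at puberty, 2853 (93.0%) were also higher in postpuberty than in neonatal testes, where independent lists would share 1154. Of the 1681 that fell, 1255 (74.7%) were also lower, where independent lists would share 298. There were 2 loci called in opposite directions, and the fold changes correlated across loci with a Pearson r of 0.94. Both comparisons cross the same break between the younger and the older ages. A large overlap follows from that break whatever its source, so the figures for independent lists do not test its cause.

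Over the 4 ages, the limma F test called 8454 of 12954 loci. The highest mean was in postpuberty for 4671 of them (55.3%), in neonatal for 2309 (27.3%), in prepuberty for 816 (9.65%) and in puberty for 658 (7.78%). By the calls at each step, 2979 loci rose from prepuberty to puberty and were called at neither other step, and 1589 fell in that way. Another 60 rose at puberty and again at postpuberty, 61 rose before puberty and then fell at puberty, 30 fell at both of the first steps, and 17 rose at puberty and fell after it. Among the tested loci, 361 had no read in any of the 6 younger libraries and an FPKM of at least 1 in each of the 5 older ones. For these the median fold was at least 189, against a floor of 3 reads over the 6 younger libraries, and 3 of the 361 had a gene number. No locus showed the reverse pattern of an FPKM of at least 1 in each younger library and no read in the 5 older ones (0 loci).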

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

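The F test gave 8175 to 8724 calls with any 1 library left out, and the replicate block, the variance trend and thinning to equal totals (added after seeing the data) left every count within 1.5 times of its main value, as did the test without a filter and the total without the 4 highest loci (also added). With the replicate block, 3038 loci rose and 1734 fell at puberty; 0 of 15 same-numbered pairs correlated above 0.1, 0 of 11 libraries correlated best with their own number, and the block ended the calls of MSTRG.98741 and MSTRG.8146 among the named loci. A pseudocount of 0.1 gave 207 rises and 434 falls for prepuberty against neonatal, 5829 and 3879 for puberty against prepuberty, 329 rises for postpuberty against puberty and 3955 falls for postpuberty against neonatal. Voom on recovered reads, also added after seeing the data, gave 176 and 392, 5873 and 3881, and 4013 falls over the whole span. An FPKM of at least 5, which leaves fewer loci to test, gave 46 and 45 in the first step, 859 and 595 in the second, 46 and 4 in the third, 912 and 591 over the span and 1611 in the F test. Median of ratios scaling gave 82, 779 and 1376 falls for the first step, the second step and the span. Quantile normalization gave 64 falls in the first step, 2943 falls in the second, 51 rises and 41 falls in the third and 2762 rises over the span. Rescaling to TPM gave 994 rises and 98 falls in the first step, 6140 and 3334 in the second and 380 rises in the third. With only the groups compared, limma gave 11 and 8 in the first step and 0 and 0 in the third, where 2514 loci had an unadjusted p under 0.05 and voom called 244 and 15; the fit then had 4 and 3 residual degrees of freedom. Without a fold threshold there were 328 and 971 in the first step, 5694 and 4103 in the second, 1638 and 43 in the third and 4487 falls over the span. For the other changes the cause was not tested. With each library left out in turn, counts ran from 79 to 139 rises and 101 to 246 falls in the first step, 3041 to 3352 and 1500 to 1877 in the second, 144 to 448 and 14 to 34 in the third, and 4553 to 4933 and 2251 to 2540 over the span. The lowest and highest falls of the first step came without prepuberty replicate 3 and without neonatal replicate 1, and 448 and 34 came without puberty replicate 2. Where a library is left out of puberty, the lone library is assumed to vary like the other groups. Among the named loci the only reversal, MSTRG.178147 with a log2 change of 0.50 over the span under quantile normalization, reflects an exchange of ranks with MSTRG.335283, as that method sets values by rank. Of the named loci, 74 of 379 alternative values lost the call and 304 kept it, with MSTRG.98741 losing it in 17 of 24, MSTRG.8146 in 16, gene7384 in 11 and MSTRG.414056 in 9. Omitting prepuberty replicate 1 and neonatal replicate 1 together, tried after seeing the data, gave 262 falls in the first step and ended the calls of MSTRG.414056, MSTRG.98741, MSTRG.8146 and gene27. The restriction to loci listed in every file was not run because all files list the same loci, and the alternatives for the gene lists were not run because no list could be matched. Depth limits the low loci: at the median implied length, an FPKM of 0.1 is under 5 reads in every library.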

Other observations

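All tests below other than the splits of the libraries were chosen only after results were seen. Loci that fell with age were longer than those that rose. Among called loci with at least 50 recovered reads in some library, the median implied length was 4359 bases for 1549 loci that fell from prepuberty to puberty (quartiles 1885 and 10352), 2120 for 2872 that rose (1051 and 4656) and 3165 for 6178 not called. Over the whole span the medians were 4216 for 2036 loci that fell and 2331 for 4368 that rose. No cause of this difference was tested.

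The break between prepuberty and puberty had both more detected loci and 4748 calls. If the gap in detected loci came from deeper sampling of the listed loci, it would shrink at equal totals, but 94.3% of it was left after thinning. Thinning acts on a fixed list of loci. It cannot show whether the deeper older libraries added more loci to that list. Scaling between libraries as the source of the number of calls was argued against. The lower of the counts under median of ratios and quantile scaling was 111% of the main count. The balance moved with the scaling, to 4475 rises and 779 falls under median of ratios and 2472 and 2943 under quantile normalization. A total does not show whether the same loci were called, so single calls can still depend on the scaling. The labels name no batch, so none was weighed, and the age of the testis is the explanation the design names, which stays open as a hypothesis.

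Prepuberty replicate 1 held a trace of 97 loci that are abundant from puberty on, with 1588 reads or 0.382% of their older level. The loci were chosen without that library (at least 500 reads in each older library, and a mean in the other younger libraries under 0.1% of the older level). Each other younger library held 128 to 231 reads or 0.0282% to 0.0592%, over loci chosen without it and without prepuberty replicate 1. With a minimum of 1000 reads, also tried, prepuberty replicate 1 stood at 0.420% over 39 loci and the other younger libraries at 0.0267% to 0.0684%. Reads carried over from the older libraries analysed here were argued against as the whole source, provided that the library's own background matched that of the other younger libraries. The mixes fitted held those 5 libraries and the mean profile of the other younger libraries. None brought the chi-square over the 97 loci below 3.71 per degree of freedom (2.31 without the 10% of loci that deviated most). The upper end of the 95% range of simulated mixes was 1.35 (0.853). These simulations held counting error only, around a fixed background. The other younger libraries themselves held 109 to 198 reads at the 97 loci, so a different background in prepuberty replicate 1 was not covered. Puberty replicate 1, which was not analysed here, was not in the mix. Material from another testis of these ages stays open. Of the 29 loci that would have at least 5 reads at one common share, 96.6% had a read. Of the same 29 loci, 75.9% had a read in prepuberty replicate 2 and 37.9% to 48.3% in the other younger libraries, so that share alone decides little. The deviation was 2.32 times the highest found for an older library thinned to as many reads and set against the others. The profile of another testis can only be assumed. An early start limited to loci higher at puberty than at postpuberty was not decided. Over the 97 loci the trace did not follow the puberty to postpuberty ratio (Spearman's rho -0.0118, 95% bootstrap interval -0.22 to 0.20). Those loci needed at least 500 reads in each older library, however, which leaves out loci that are low at postpuberty. A testis further along than the others of its age, and material from an age not measured here, were not tested and stay open.

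From puberty to postpuberty, 163 loci rose and 18 fell. Scaling between libraries was argued against as the whole source of this imbalance by median of ratios scaling only. There, 81.7% of the calls were higher (95% Wilson interval 74.5% to 87.2%, with loci taken as independent), against 90.1% with the authors' scaling. The share under TPM, 95.2%, decides nothing here. FPKM sums averaged 61076 in puberty and 61228 in postpuberty libraries, so TPM hardly changes the scaling between these ages. The listed loci as a set took more of the scaling total in postpuberty (16.9% ± 0.822, SD, n = 3) than in puberty libraries (14.2% ± 0.993, n = 2). The test first used was the share under quantile normalization, 55.4%, which favoured scaling as the source; it was replaced after its outcome was seen, because that method makes the distributions equal whatever the cause. A single puberty library was argued against as its source, because at least 86.8% of the calls were higher without either of them. The simulation of this comparison called 2 of 34 loci raised and 1 of 33 lowered 2-fold. It called 33 of 34 and 16 of 33 at 4-fold, and 33 of 33 and 27 of 33 at 8-fold. Its changes started from puberty means of at least 1 FPKM, so lowered loci moved toward the pseudocount, and it cannot decide on uneven power. The share of calls that were higher was 95.9% at a pseudocount of 0.1 and 94.2% with voom. Without a fold threshold, 1638 loci rose and 43 fell. These values argue against the pseudocount and the fold threshold as the source of the imbalance. Other forms of uneven power, and further maturation between these ages, the biological difference the design names, were not tested and stay open.

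Other splits of the libraries were also counted. For prepuberty against neonatal, the real split of the 6 libraries gave 268 calls and the highest of the other 9 splits gave 1. For postpuberty against neonatal, the real split gave 7171 calls and the highest of the other splits gave 0. In each case 1 of the 10 splits, the real one, gave as many calls, and 10 splits are too few for a share under 0.05.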
